A study of Homo sapiens with 36 samples.

How the data were processed

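Gene expression was measured by RNA sequencing in 36 libraries of A498 and 786-O, established human lines of clear cell renal cell carcinoma. Each line was used as parental cells and as cells selected for resistance to sunitinib, an inhibitor of VEGF, PDGF and other receptor tyrosine kinases. Per the labels, selection used 2 µM sunitinib for A498 and 4 µM for 786-O. Each of the 4 cell states (2 lines, resistant or parental) was treated with atezolizumab, avelumab or durvalumab, antibodies that bind PD-L1, for 24 h at 10 mg/mL, the unit as the labels write it. Each of the 12 groups held 3 libraries, and untreated libraries were not analysed here. Each cell state carries 1 batch label of its own.

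The authors deposited raw counts of reads per gene, not normalized, in 1 table with a column for each library. Per the submitters' processing notes, the tools used were bcl2fastq 2.19.0, Trimmomatic 0.36.6, HISAT2 2.1.0 and featureCounts 1.6.3, with the genome build GRCh38. Per the labels' protocols, libraries were made with a stranded mRNA kit, which selects polyadenylated RNA. The annotation release and the strand setting of the counting are not given in the sources used here. Genes that share at least 10% of their exonic length with a neighbour on either strand, and near copies of other genes, are therefore marked as uncertain where they are named. Shares under 10% were found for TAP1 (9.5%), CCN2 (8.3%), LARP7 (7.4%), SREBF1 (6.9%), SCN8A (6.0%), PSMB9 (5.7%) and HPD (5.0%), and shares under 5% for ARRDC3, B3GALNT1, C1S, CDK5RAP3, CEP152, CMPK2, HIF1A, LOX, MX1, NNT, OAS1, OSBPL1A, PDGFD, PTPRN, SGSH, STARD4, TM7SF2 and TP53I3, whose values are uncertain for the same reason. Polyadenylated RNA captures transcripts of replication-dependent histone genes poorly, so their values reflect a minor form of these transcripts.

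The table held 45478 Ensembl gene identifiers, 45283 of them paired with a symbol by the reference tables. Of these identifiers, 43799 were in GENCODE release 29, from which coordinates on GRCh38 were taken, 18733 were protein coding and 3555 had 0 counts in all libraries. All columns were used, and no line lacked a gene. Totals ran from 19994882 to 58122896 counts per library. No library was a copy of another. Reads were counted without molecular identifiers, so intervals and limits cover counting error only.

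Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups as the design (count minimum 10, total minimum 15). Libraries were scaled by TMM, and a model of group means was fitted by robust quasi-likelihood. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Antibodies were compared within each cell state, from its 9 libraries, in pairs and by a test with 2 degrees of freedom. Resistant and parental cells of a line were compared over its 18 libraries, averaged over the antibodies and under each antibody. The same fit tested whether antibody differences depended on the cell state. All 36 libraries entered the test of whether the resistant minus parental change differed between lines. Standard errors of log2 changes were derived from the quasi-likelihood F statistic. CPM values were computed from the deposited counts over the raw total of each library, without TMM factors. The log2 CPM behind correlations and principal components used TMM library sizes. Where 1 state held 1 to 3 counts of a gene in all, the ratio is given with its exact 95% counting interval. Where it held 0, the fold is a lower bound at 3 counts over the group.

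Gene lists, 35 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested members. Each list was also tested with an estimated correlation and with fry. The lists cover pathways of the tumour and the drugs, leukocyte markers, and endothelial and fibroblast markers. The design, the tests, the lists, the rule for named genes and most alternative settings were fixed before the data were examined.

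Genes named in the text had to have a symbol. For resistance in each line they were the 12 highest and the 12 lowest averaged log2 changes. These had to pass under every antibody, with the same sign, and reach at least 5 CPM in the higher state. For each antibody pair they were the 3 highest and the 3 lowest changes among genes past the threshold with at least 5 CPM in the higher group and no overlap between the libraries of the groups. Chance gives no overlap for 10% of unchanged genes in 3 against 3 libraries. Where no gene passed, the 2 genes of lowest p were taken as values that did not pass. For interactions, the 4 genes of lowest p on each side were taken. Of a list, up to 4 members with the largest change and at least 1 CPM were taken, and CD274 was always reported. Unnamed loci, pseudogenes and multi-copy paralogs were left out, among them genes with a near copy on the other sex chromosome. Genes outside the rule are named as such.

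Alternative settings were DESeq2 1.42.0, RLE scaling factors, no filter, a stricter filter (at least 5 CPM in 3 libraries), a fit on only the libraries compared, a replicate block, a minimum change of 2-fold, and leaving out each library in turn. Further settings chosen after the data were seen were thinning to the smallest library, a mitochondrial covariate, removal of each library's gene length trend, and a comparison against 786-O parental libraries. Other splits of the libraries, 100 at most for each result, were refitted in the same way.

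The tests were checked on simulated counts in which 200 genes were changed by known folds. For avelumab against atezolizumab in A498 parental cells (18190 genes), 66% of genes changed 1.25-fold, 86% changed 1.5-fold and 94% changed 2-fold were recovered. For the interaction in 786-O (19195 genes), these shares were 30%, 78% and 92%. For A498 resistance (18854 genes) they were 78%, 96% and 100%. Unchanged genes called beside them numbered 15, 8 and 20 in the same order, with 86.5%, 75% and 93.5% of the 200 changed genes recovered, so the share of false calls lay above 5% in these simulations. The simulated counts were drawn independently for each gene and library, without deviations shared by the genes of a library. The shares recovered and falsely called may therefore differ in the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Results for some genes that met the same rules as those named are not reported here.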

Results

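The series set sunitinib-resistant against parental cells of the clear cell renal carcinoma lines A498 and 786-O, under atezolizumab, avelumab or durvalumab, 3 antibodies that bind PD-L1. Raw RNA-seq counts were analysed for 36 libraries in 12 groups of 3, which form 4 cell states of 9 libraries. Total counts averaged 24492963 ± 5098781 (SD, n = 9) in the libraries labelled A498 resistant and 33861245 ± 7108433 in A498 parental. They averaged 41595466 ± 5559592 in 786-O resistant and 39070460 ± 7924537 in 786-O parental, with a range of 19994882 to 58122896 over all libraries. Each cell state carries its own batch label, so resistance and batch cannot be told apart, whereas antibodies were compared inside 1 batch. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are given as CPM ± SD over the 9 libraries of a state or the 3 of a group, and log2 changes ± SE.

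CD274, the gene of PD-L1 (ENSG00000120217.14, chromosome 9, 5450503 to 5470566 on GRCh38), was detected in all states. Its level was 8.82 ± 0.824 CPM in the libraries labelled A498 resistant and 8.18 ± 0.501 in A498 parental. It was 8.92 ± 0.38 CPM in 786-O resistant and 10.3 ± 0.925 in 786-O parental (n = 9 each). In 786-O, CD274 was 1.24-fold lower in resistant cells (log2 change -0.31 ± 0.046, edgeR adjusted p = 2.76e-07), with log2 changes of -0.42 under atezolizumab, -0.28 under avelumab and -0.23 under durvalumab. The durvalumab call (adjusted p = 0.0117) ended without 786-O parental durvalumab replicate 3 (adjusted p = 0.0511) and with the strict filter (adjusted p = 0.0686). The difference labelled as A498 resistance was 0.02 ± 0.052 (adjusted p = 0.692). CD274 did not differ between any antibody pair in any state, with a smallest adjusted p of 0.177.

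The libraries labelled A498 resistant carried a profile close to that of 786-O. HIF1A, a member of the hypoxia list chosen for this paragraph after the data were seen, which encodes the hypoxia-inducible factor subunit that 786-O cells are known not to make, was at 294 ± 7.4 CPM in A498 parental. Its level was 8.99 ± 0.49 CPM in the libraries labelled A498 resistant, 8.71 ± 0.42 in 786-O resistant and 9.36 ± 0.57 in 786-O parental. Across 15400 genes, which are not independent replicates, the mean profile of the libraries labelled A498 resistant correlated with 786-O resistant at r = 0.985 and with 786-O parental at r = 0.937. With A498 parental r was 0.805, equal to that between the parental lines. Single libraries gave r of 0.977 to 0.987 against 786-O resistant and 0.798 to 0.807 against A498 parental, and libraries of 1 state gave 0.9945 to 0.9977 among themselves. No library was moved to another group, and every A498 resistance value below is a difference between libraries as labelled.

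**Figure D1:**
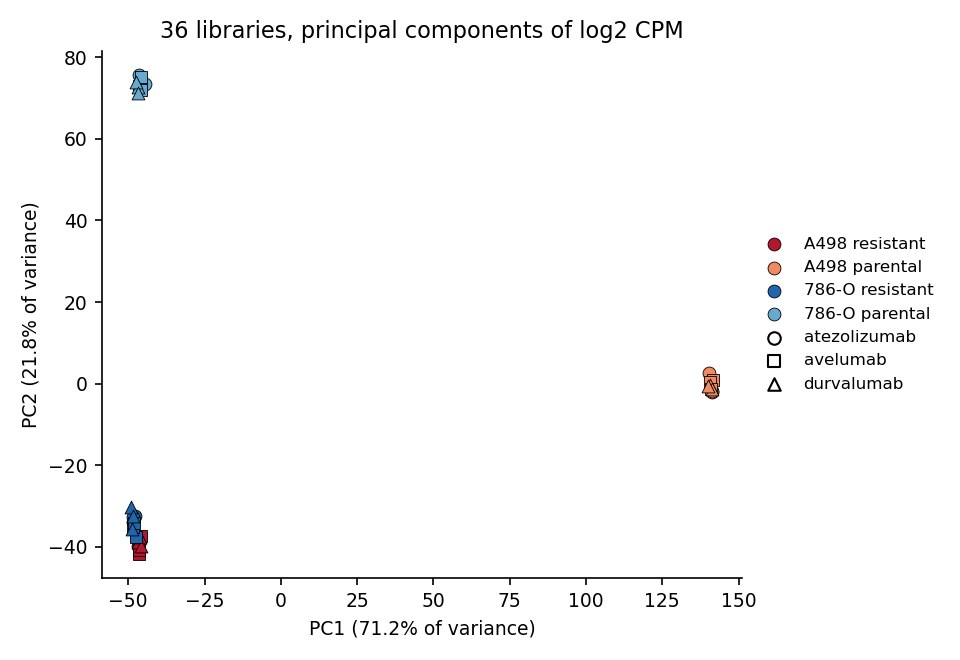
Principal components of log2 CPM over the 36 libraries, 1 point per library, coloured by cell state and shaped by antibody. Component 1 (71.2% of the variance) separates A498 parental from the other 3 states, and component 2 (21.8%) separates 786-O parental from both sets of libraries labelled resistant.

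Genes at opposite extremes between the libraries labelled A498 resistant and A498 parental were each near 0 on 1 side. UCA1, a long noncoding RNA (chromosome 19, 15828206 to 15836326), was at 196 ± 6.37 against 0.0548 CPM. NNT, the mitochondrial transhydrogenase that makes NADPH (chromosome 5, 43602692 to 43707405), was at 245 ± 4.01 against 0.158 CPM. GSTP1, which conjugates glutathione (chromosome 11, 67583595 to 67586656), was at 490 ± 15.5 against 0.33 ± 0.116 CPM. In the opposite direction, MLPH, which links melanosomes to myosin (chromosome 2, 237485428 to 237555318), was at 0.0858 against 140 ± 13.2 CPM. TDRD9, a helicase of the piRNA pathway, was at 0.0734 against 50.9 CPM. In 786-O resistant and parental libraries UCA1 was at 196 and 37.9 CPM, GSTP1 at 470 and 348, and MLPH at 0.0267 and 1.59.

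The log2 changes were 11.88 ± 0.071 for UCA1, 10.52 ± 0.053 for NNT, 10.45 ± 0.051 for GSTP1, -10.96 ± 0.07 for MLPH and -9.70 ± 0.098 for TDRD9. LINC01764 was higher by 10.60, but 73.1% of its exonic length overlaps UCA1 on the opposite strand, so it is uncertain, as is UCA1 (11.8%). ZNF69 gave a count ratio of 1820 (95% interval 502 to 15000) and ZFP28 one of 2930 (525 to 116000), while ZNF415 was at least 620-fold higher. ENPP5, a phosphodiesterase family gene, was at least 648-fold higher. ADAMTS10, a secreted metalloprotease, was at 0.0408 against 26.7 CPM and GDA, guanine deaminase, at 0.0499 against 25.1 CPM in pooled counts (9 and 11 counts in the libraries labelled A498 resistant). Count ratios in the lower direction were 2450 (837 to 11900) for ZFP42, a zinc finger gene of pluripotent cells, and 3000 (538 to 118000) for TNFAIP8L3. They were 723 (247 to 3510) for HMX1, a homeobox gene, 1020 (348 to 4940) for PRTFDC1 and 1530 (275 to 60600) for TSPAN7, a tetraspanin. NPTX2, a pentraxin, gave 971 (269 to 8020), and GSTM1, uncertain because 22.3% of its exons are shared with GSTM2, gave 1620 (555 to 7870). Of 19458 genes tested with edgeR, 17155 passed, 8595 higher and 8560 lower. At least 2-fold changes numbered 2923 higher and 3262 lower, and each antibody alone gave 15388 (atezolizumab), 15647 (avelumab) and 15510 (durvalumab) genes. Each state has its own batch, and the line of the libraries labelled A498 resistant is in doubt, so these values cannot be assigned to resistance.

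**Figure D2:**
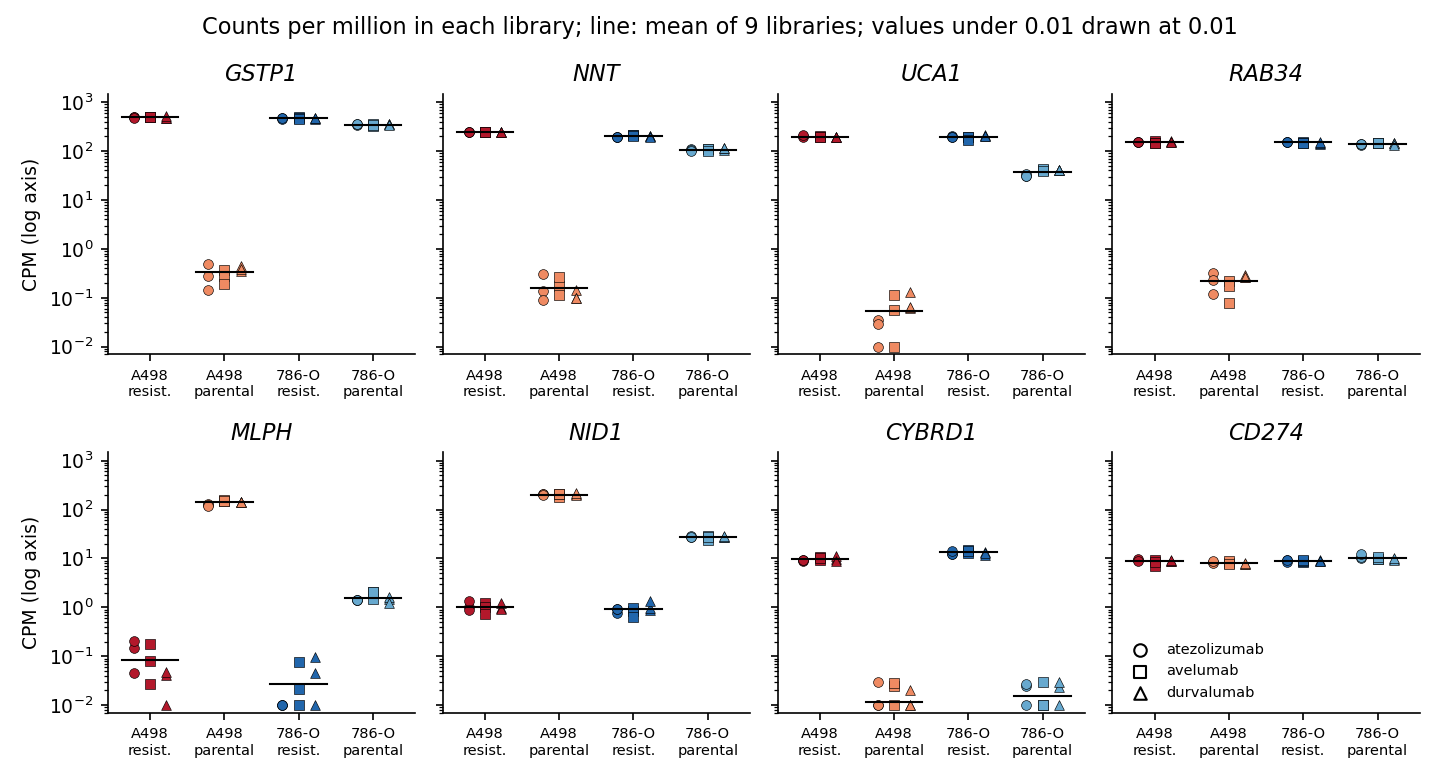
CPM of 8 genes in each of the 36 libraries (points, log axis, values under 0.01 drawn at 0.01), by cell state, with lines at the mean of 9 libraries. GSTP1, NNT, UCA1 and RAB34 are near 0 in A498 parental alone, MLPH and NID1 are highest there, CYBRD1 is near 0 in both parental states, and CD274 lies between 8.18 and 10.3 CPM on average.

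NRF2 target genes, which detoxify electrophiles, were lower in the libraries labelled A498 resistant. All 32 tested members passed lower (32 adjusted over the list alone), with a median log2 change of -1.65 and a list call that held with an estimated correlation (camera adjusted p = 0.0137). AKR1B10, an aldo-keto reductase, fell by 8.30 ± 0.054 on the log2 scale, from 1640 ± 190 to 5.48 ± 0.56 CPM. AKR1C2 (-9.16 ± 0.124), AKR1C1 (-7.76) and AKR1C3 (-5.96) are near copies of each other and uncertain. Cholesterol synthesis genes were higher in 24 of 25 and lower in 1 (24 and 1 adjusted over the list alone), among them SC5D (2.36) and HMGCS1 (1.71), uncertain because 15% of its exonic length overlaps an antisense gene. That call was lost with an estimated correlation (adjusted p = 0.232).

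Complement genes were lower in 8 of 11 and higher in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.0934 with an estimated correlation), with C1S at -5.23 and C1R, its partner protease, at -4.70, uncertain because it shares 11.4% of its exonic length with a neighbour. Sunitinib target kinases and their ligands were lower in 11 of 14 and higher in 3 (11 and 3 adjusted over the list alone; adjusted p = 0.0788 with an estimated correlation). Among these, PDGFD, a PDGF receptor ligand, was at -6.22 and the receptor PDGFRB at 4.23. Interferon response genes were higher in 48 of 63 and lower in 12 (48 and 12 adjusted over the list alone), with MX2 at 5.46 and MX1 at -2.73 (adjusted p = 0.435 with an estimated correlation). The p53 targets were lower in 21 and higher in 6 of 28 (21 and 6 adjusted over the list alone; adjusted p = 0.139 with an estimated correlation), with TP53I3 at -4.34. Leukocyte markers were higher in 2 and lower in 5 of 7 tested, and endothelial and fibroblast markers higher in 4 and lower in 1 of 6. The counts adjusted over the list alone were equal. Neither list was called (adjusted p = 0.197 and 0.454), although LUM, a matrix proteoglycan, was higher by 9.83. Of 35 lists 11 were called, 3 up and 8 down, and 1 with an estimated correlation. For the same reasons none of these lists can be assigned to resistance.

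In 786-O resistant cells, CYBRD1 and LGALS9 were among the genes that rose most, and PLEK2 and NID1 among those that fell most. CYBRD1, a ferric reductase (chromosome 2, 171522247 to 171558133), was at 13.3 ± 1.17 CPM in resistant and 0.0151 ± 0.0145 in parental libraries (log2 change 9.52 ± 0.156). LGALS9, which encodes galectin-9 (chromosome 17, 27629798 to 27649560), was at 13.2 against 0.0601 CPM (7.55 ± 0.151). NID1, a basement membrane glycoprotein, fell by 5.00 ± 0.063, from 27.3 to 0.917 CPM, and PLEK2, a pleckstrin family gene, fell by 5.85 ± 0.067.

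Other genes among the highest were OSBPL1A, an oxysterol-binding protein (6.93 ± 0.084), SCN8A, a sodium channel (6.85 ± 0.097), and CERS4, a ceramide synthase (6.83 ± 0.153). APBA1 (6.37), DHRS2 (6.35), LINC03061 (5.61) and COL4A4, a basement membrane collagen (5.55), followed. IFITM1, an antiviral membrane protein, was higher by 5.63 ± 0.115 but shares 32.5% of its exonic length with IFITM2. Among the lowest were MALL (-5.99), B3GALNT1, a glycosyltransferase (-5.93 ± 0.063), PRTFDC1 (-5.40), IGFBP4, which binds insulin-like growth factors (-5.14), P2RY2, a nucleotide receptor (-4.96), and ZNF300 (-4.85). ZNF22 (-6.01) and LRRC34 (-5.60) overlap neighbours over 31.2% and 25.8% of their exonic length and are uncertain. Of 19369 genes, 16232 passed with edgeR, 8443 higher and 7789 lower, and 2811 were higher and 1098 lower at least 2-fold. Each antibody alone gave 13932 (atezolizumab), 14168 (avelumab) and 13800 (durvalumab) genes. Resistance and batch label cannot be told apart in these values, and the strict filter, which tests fewer genes, gave 10787. The mean profile of 786-O resistant libraries correlated with 786-O parental at r = 0.942, less than with the libraries labelled A498 resistant (0.985). Why the 2 sets labelled resistant were closer to each other than to 786-O parental was not tested.

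Interferon response genes rose together in 786-O resistant cells. Of 63 tested, 62 were higher and 0 lower (62 and 0 adjusted over the list alone), with a median log2 change of 1.80, among them OAS2, an antiviral oligoadenylate synthetase (5.27 ± 0.08), CMPK2 (4.80 ± 0.057) and MX2 (4.68 ± 0.098). Class I antigen presentation genes were higher in 19 and lower in 1 of 22, with TAP1, a peptide transporter, at 1.89. HLA-F (3.59) and HLA-B (2.26) are members of a multigene family and uncertain. Replication-dependent histone genes were higher in 16 of 16, for example H2BC5 (3.10) and H1-2 (2.42), both uncertain as members of a multigene family. Lysosome genes were higher in 39 and lower in 9 of 54, led by GPNMB, a lysosomal and melanosomal glycoprotein (4.36 ± 0.087), SGSH (2.13) and NEU1 (1.88). These 4 lists held with an estimated correlation (camera adjusted p = 0.021 for interferon and for lysosome genes, 0.0303 for class I and 0.0297 for histones). The counts adjusted over the list alone were equal for each. Leukocyte markers were higher in 4 and lower in 2 of 10 and endothelial and fibroblast markers higher in 5 and lower in 1 of 7, with equal counts adjusted over the list alone, and neither was called (adjusted p = 0.857 and 0.46).

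Ribosomal protein genes were lower in 74 of 74 in 786-O resistant cells (74 adjusted over the list alone), with a median of -0.73 and RPL10 at -1.20. Their share of counts was 3.32% in resistant and 4.95% in parental libraries, and pseudogenes make single members uncertain (adjusted p = 0.253 with an estimated correlation). Cell cycle genes were lower in 48 and higher in 6 of 59 (48 and 6 adjusted over the list alone), with RRM2, a subunit of ribonucleotide reductase, at -1.25 and CDC45, a replication helicase component, at -1.05 (adjusted p = 0.122 with an estimated correlation). Cholesterol synthesis genes were higher in 21 and lower in 2 of 25 (21 and 2 adjusted over the list alone), with TM7SF2 at 1.58 and HMGCS1 at 1.36 (adjusted p = 0.0974 with an estimated correlation). Nuclear genes of oxidative phosphorylation were lower in 59 and higher in 7 of 77 (59 and 7 adjusted over the list alone; adjusted p = 0.609 with an estimated correlation). Of 35 lists 16 were called, 8 up and 8 down, and 4 with an estimated correlation. Hypoxia-inducible factor targets (15 higher, 20 lower of 38) were not called (adjusted p = 0.403), although LOX, which crosslinks collagen, was at -3.90. Checkpoint ligands and receptors (11 higher, 8 lower of 21) were not called either (adjusted p = 0.133), although VTCN1, the B7-H4 gene, was at 6.01. Counts adjusted over the list alone were equal for both. Resistance cannot be told apart from batch in these lists.

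**Figure D3:**
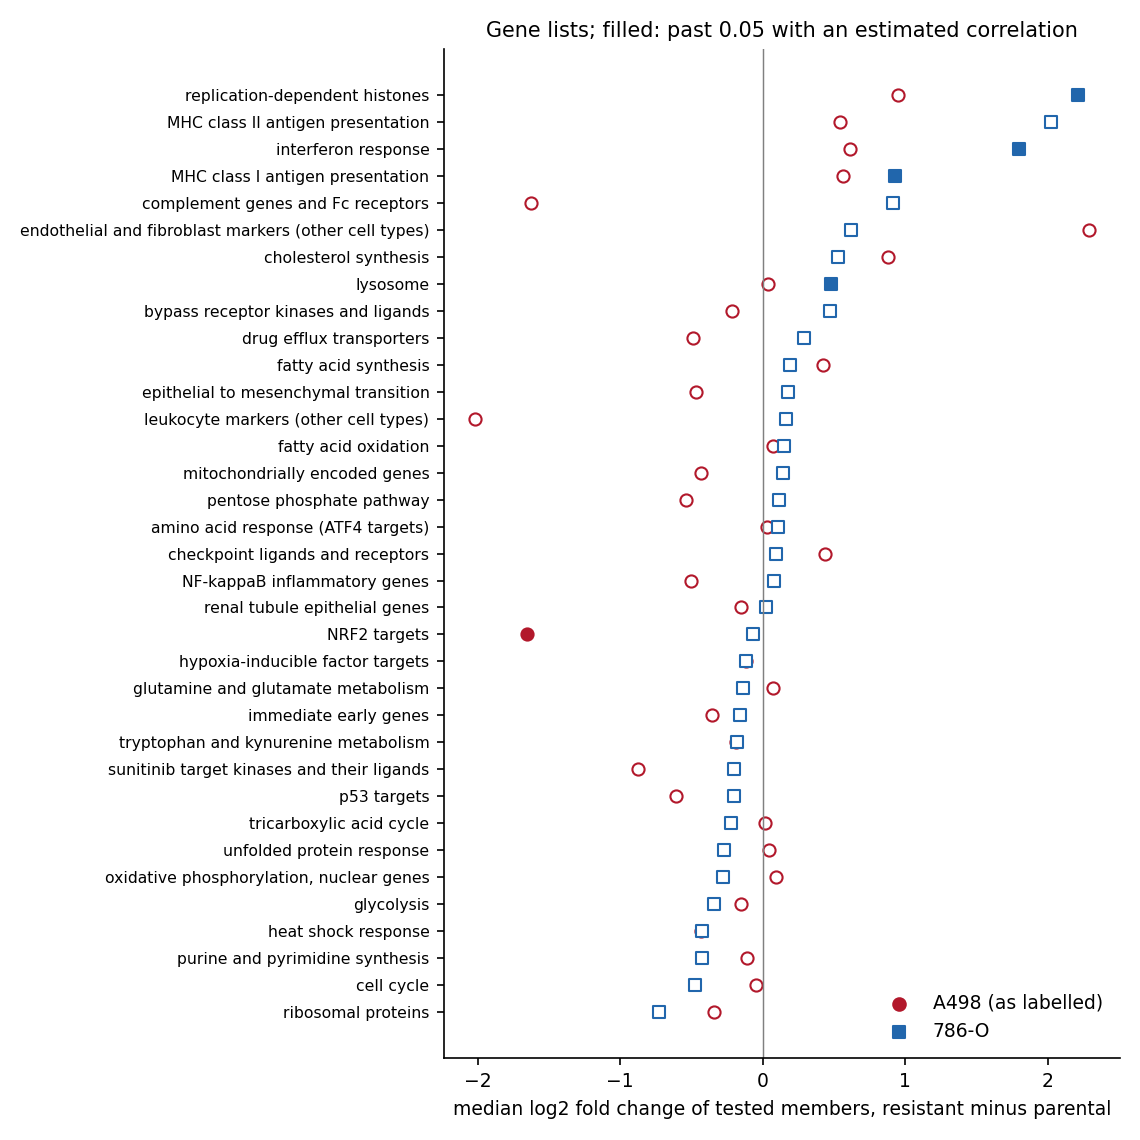
Median log2 change, resistant minus parental, of 35 gene lists in A498 as labelled and in 786-O, with filled points for lists past an adjusted p of 0.05 with an estimated correlation. Interferon response (1.80) and histone genes lie far to the right in 786-O, and NRF2 targets (-1.65) far to the left in A498 as labelled.

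The resistant minus parental change differed between the lines as labelled for 16683 of 20752 genes, 8265 higher and 8418 lower in 786-O (edgeR). C1S, a complement protease, differed by 7.39, TNNT1, a troponin, by 6.83, JUP, a junction protein, by 5.81 and ANPEP, a membrane aminopeptidase, by 5.07. GSTP1 (-10.14 ± 0.064), NNT (-9.74 ± 0.067) and RAB34, a small GTPase (-9.41), differed in the opposite direction. ANPEP was at 69.7 and 864 CPM in the libraries labelled A498 resistant and A498 parental and at 130 and 46.7 CPM in 786-O resistant and parental. CD274 differed by -0.35 ± 0.069 (adjusted p = 1.03e-05). Each state has its own batch, and the line of the libraries labelled A498 resistant is in doubt, so the difference cannot be assigned to resistance.

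In A498 parental cells, 21 of 63 interferon response genes were lower and 17 of 40 ATF4 target genes higher under avelumab than under atezolizumab, list calls that were lost with an estimated correlation (adjusted p = 0.259 for each). Of the interferon response genes 0 were higher (44 lower adjusted over the list alone). Those lower included BATF2, an interferon-induced transcription factor (-0.50 ± 0.13), USP18, which removes ISG15 (-0.45 ± 0.077), and CMPK2. Of the ATF4 targets, which answer amino acid shortage, 0 were lower (28 higher adjusted over the list alone), and those higher included CBS, cystathionine beta-synthase (0.50 ± 0.101), and SLC38A2, an amino acid transporter (0.33 ± 0.037). Class I antigen presentation genes were lower in 7 of 21 (13 adjusted over the list alone), for example PSMB9, an immunoproteasome subunit (-0.22). The class I call was lost as well (adjusted p = 0.0834). The share of mitochondrial transcripts was 2.53% ± 0.089 in the atezolizumab libraries and 2.75% ± 0.134 in the other 6 (exact two-sided permutation p = 0.0357, adjusted p over 4 states = 0.143).

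Durvalumab against atezolizumab gave 12 interferon response genes lower of 63 (19 adjusted over the list alone; adjusted p = 0.354 with an estimated correlation) in A498 parental cells. CCL5, a chemokine, was at -0.35 and IFITM3, uncertain because 21.3% of its exonic length overlaps an antisense gene, at -0.29. Class I genes were lower in 6 of 21 (14 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation). Genes of matrix and adhesion on the mesenchymal list were higher in 3 of 36, among them CCN2 (0.52) and CCN1 (0.48), both secreted matricellular proteins (3 higher and 2 lower adjusted over the list alone; adjusted p = 0.354 with an estimated correlation).

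The genes named for A498 parental cells changed by less than 2-fold between antibodies. Of all genes past the threshold, 18 changed at least 2-fold for avelumab minus atezolizumab and 16 for durvalumab minus atezolizumab. LGALS9 was at 6.95 ± 1.1 CPM under atezolizumab, 4.14 ± 0.3 under avelumab and 4.13 ± 0.609 under durvalumab (n = 3 each). Its log2 change was -0.75 ± 0.119 for avelumab (edgeR adjusted p = 0.000463) and -0.78 ± 0.118 for durvalumab, each against atezolizumab. HPD, an enzyme of tyrosine breakdown, was lower by the same comparisons (-0.74 ± 0.12 and -0.83 ± 0.12). ID3, an inhibitor of helix-loop-helix factors, was at -0.72 ± 0.11 and -0.63 ± 0.108. MIR503HG, a microRNA host gene (0.60 ± 0.107), and LINC02783 (0.63 ± 0.125), which overlaps a neighbour over 19.1% of its exonic length, were higher under avelumab. CDK5RAP3 (0.79 ± 0.127) and UCN2, a peptide of the CRF family (0.71 ± 0.105), were higher under durvalumab than under atezolizumab, UCN2 with 19.5% of its exonic length shared with PFKFB4. Durvalumab exceeded avelumab for C4orf48 (0.48 ± 0.085), RTN4R, a Nogo receptor (0.37 ± 0.07), and COMTD1 (0.34 ± 0.066).

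The ID3 call for avelumab (adjusted p = 0.016) ended without avelumab replicate 2 or 3 (adjusted p 0.0572 to 0.102). The ID3 call for durvalumab (adjusted p = 0.0278) ended without atezolizumab replicate 1 or 3, avelumab replicate 1, 2 or 3 or durvalumab replicate 1 (0.0502 to 0.103). That of C4orf48 (adjusted p = 0.0162) ended without avelumab replicate 2 or durvalumab replicate 1 or 2 (0.14 to 0.406) and with the strict filter (0.0622). Those of RTN4R and COMTD1 (adjusted p = 0.0331 each) ended without avelumab replicate 1 or 2 or any 1 durvalumab replicate (0.0626 to 0.727 for each gene). With DESeq2 both RTN4R and COMTD1 were at an adjusted p of 0.13 and with the strict filter at 0.0663.

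In all, 704 of 18372 genes differed among the antibodies in A498 parental cells (edgeR). Avelumab minus atezolizumab gave 315 higher and 308 lower genes, with a median size of 0.219 on the log2 scale. Durvalumab minus atezolizumab gave 327 higher and 188 lower, and durvalumab minus avelumab 11 higher and 0 lower, where 1264 genes were at an unadjusted p under 0.05 and DESeq2 called 7 in all. Without 1 library, the 704 genes became 395 (atezolizumab replicate 1), 233 (atezolizumab replicate 3), 358 (avelumab replicate 2) and 359 (durvalumab replicate 1). The 623 genes for avelumab became 316 without atezolizumab replicate 1, 259 without atezolizumab replicate 3 and 141 without avelumab replicate 2. The 515 genes for durvalumab became 130 without atezolizumab replicate 3 and 115, 316 and 294 without durvalumab replicates 1, 2 and 3. The 11 genes became 4, 0 and 136 without avelumab replicates 1, 2 and 3 and 2 and 0 without durvalumab replicates 1 and 2. With the mitochondrial percent of each library as a covariate, chosen after the data were seen, 68 genes passed the test among the antibodies. With no filter the 704 genes became 1099 and the 11 genes 100, and the 11 became 0 with the strict filter and 1 when only the 6 libraries compared were fitted.

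**Figure D4:**
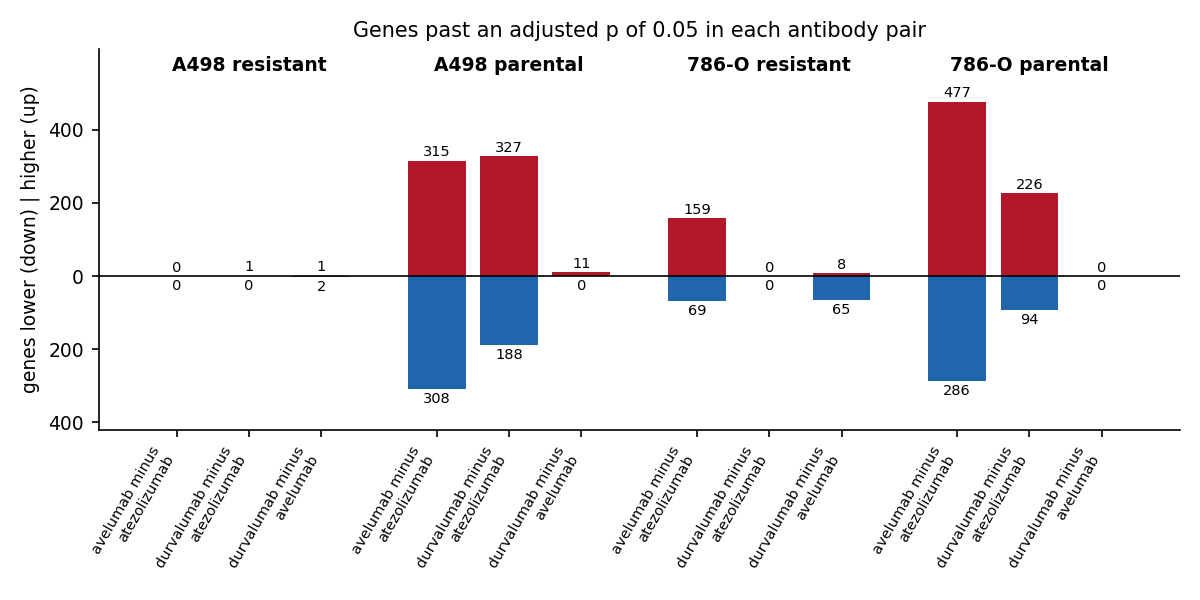
Genes past an adjusted p of 0.05 for each antibody pair in each cell state, bars up for higher and down for lower. Under avelumab against atezolizumab 315 genes are higher in A498 parental and 477 in 786-O parental, and the libraries labelled A498 resistant have at most 3 genes in a pair.

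In 786-O parental cells, 13 of 24 cholesterol synthesis genes under durvalumab and 8 of 24 under avelumab were higher than under atezolizumab, list calls that were lost with an estimated correlation (adjusted p = 0.13 and 0.271). Under durvalumab 0 were lower (20 higher adjusted over the list alone), and those higher included INSIG1, which retains SREBP in the endoplasmic reticulum (0.39), and HMGCS1 (0.36). Under avelumab 19 were higher adjusted over the list alone, for example DHCR7 (0.31). Fatty acid synthesis genes were higher in 5 of 21 under durvalumab (9 higher and 1 lower adjusted over the list alone), with SCD, a stearoyl desaturase, at 0.47 and FASN, fatty acid synthase, at 0.25. Under avelumab these were higher in 6 of 21 (9 higher and 1 lower adjusted over the list alone), with SREBF1, their transcription factor, at 0.41. With an estimated correlation the durvalumab fatty acid call held (adjusted p = 0.04). That for fatty acids under avelumab was lost (0.0943).

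Interferon response genes in 786-O parental cells were lower in 11 and higher in 1 of 62 under avelumab (23 and 2 adjusted over the list alone; adjusted p = 0.534 with an estimated correlation). OAS2 was at -0.84 ± 0.184 and EPSTI1 at -0.67. Under durvalumab 4 were lower and 1 higher (14 and 2 adjusted over the list alone; adjusted p = 0.773 with an estimated correlation). Immediate early genes were higher in 6 and lower in 1 of 33 under avelumab (10 and 4 adjusted over the list alone; adjusted p = 0.557 with an estimated correlation), with DUSP6, a phosphatase of ERK, at 0.48 (uncertain, 40.5% of its exonic length overlapped by an antisense gene) and KLF2 at 0.39.

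EGR1, a growth factor-induced transcription factor (chromosome 5, 138465490 to 138469315), was at 2.38 ± 0.32 CPM under atezolizumab, 18.5 ± 6.06 under avelumab and 9.68 ± 4.45 under durvalumab in 786-O parental cells (n = 3 each). It was 7.84-fold higher under avelumab than under atezolizumab (log2 change 2.97 ± 0.499, edgeR adjusted p = 0.0308). VAV3, a guanine nucleotide exchange factor, was 4.09-fold higher (2.03 ± 0.293, adjusted p = 0.0142). ATOH8, a helix-loop-helix factor, was 1.96-fold higher under avelumab (0.97 ± 0.101) and 1.76-fold higher under durvalumab (0.81 ± 0.104). Lower under avelumab were OAS1 (-0.60 ± 0.146), MX1 (-0.59 ± 0.129) and TRAF1, a TNF receptor adaptor (-0.50 ± 0.122). Lower under durvalumab were IFI6 (-0.43 ± 0.077) and SDSL, a serine dehydratase-like enzyme (-0.42 ± 0.064). PINK1 (-0.19 ± 0.034) and JSRP1 (-0.18 ± 0.034) were the genes of lowest p between durvalumab and avelumab and did not pass (adjusted p = 0.136 for each). Both overlap a gene on the opposite strand, over 39.4% and 12.1% of their exonic length.

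The EGR1 call ended without atezolizumab replicate 1, 2 or 3, avelumab replicate 2 or 3 or durvalumab replicate 2 (adjusted p 0.0501 to 0.112). That of VAV3 ended without atezolizumab replicate 1, 2 or 3 (0.0537 to 0.0636). That of OAS1 (adjusted p = 0.0491) ended without atezolizumab replicate 3 or any 1 avelumab or durvalumab replicate (0.0603 to 0.168). That of MX1 (adjusted p = 0.0183) ended without atezolizumab replicate 3 or avelumab replicate 2 or 3 (0.0598 to 0.114). That of TRAF1 (adjusted p = 0.0445) ended without atezolizumab replicate 1 or 3, avelumab replicate 2 or 3 or durvalumab replicate 1 or 2 (0.0518 to 0.141). That of IFI6 (adjusted p = 0.00967) ended without durvalumab replicate 2 (0.0654). PINK1 passed without atezolizumab, avelumab or durvalumab replicate 1 (0.0181 to 0.0351), with DESeq2 (0.00548) and with no filter (0.000604). JSRP1 passed without the same libraries (0.0181 to 0.0462), with DESeq2 (0.00895) and with no filter (0.000575).

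Of 17577 genes, 618 differed among the antibodies in 786-O parental cells (edgeR). Avelumab minus atezolizumab gave 477 higher and 286 lower genes and durvalumab minus atezolizumab 226 higher and 94 lower. Durvalumab minus avelumab gave 0 with edgeR, where 1899 genes were at an unadjusted p under 0.05 and DESeq2 called 30. The 618 genes became 305 without atezolizumab replicate 3, 299 without avelumab replicate 2, and 1235 and 316 without durvalumab replicates 1 and 2. The 763 genes for avelumab became 412 and 410 without atezolizumab replicates 1 and 3 and 244 and 415 without avelumab replicates 2 and 3. The 320 genes for durvalumab became 186 and 118 without atezolizumab replicates 2 and 3 and 536, 104 and 193 without durvalumab replicates 1, 2 and 3. The count of 0 became 18 without atezolizumab replicate 1, 72 without avelumab replicate 1 and 222 without durvalumab replicate 1. With no filter the 618, 320 and 0 genes became 1400, 643 and 299, fitting only the 6 libraries compared turned 0 into 12, and the mitochondrial covariate turned 618 into 373.

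In 786-O resistant cells, DHRS3, EGR1 and SEMA5B were higher under avelumab than under either other antibody. DHRS3, a retinaldehyde reductase (chromosome 1, 12567910 to 12617731), was at 14.9 ± 2.66 CPM under avelumab, 4.43 ± 0.408 under atezolizumab and 5.82 ± 0.416 under durvalumab (n = 3 each). EGR1 was at 5.5 CPM under avelumab against 1.79 and 1.83, and SEMA5B, a semaphorin, at 8.97 against 4.34 and 5.05. Against atezolizumab the log2 changes were 1.72 ± 0.116 for DHRS3 (edgeR adjusted p = 9.05e-08), 1.58 ± 0.135 for EGR1 (8.82e-07) and 1.02 ± 0.107 for SEMA5B (1.49e-05). Durvalumab minus avelumab gave -1.36 ± 0.11 for DHRS3, -1.59 ± 0.132 for EGR1 and -0.83 ± 0.103 for SEMA5B.

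Inflammatory genes on the NF-kappaB list were lower under avelumab than under atezolizumab in 16 of 39 and higher in 0 (23 lower adjusted over the list alone) in 786-O resistant cells. CCL20 (-0.69 ± 0.14), CXCL1 (-0.64) and CXCL2 (-0.59) are chemokines, CXCL1 and CXCL2 uncertain as near copies, and TNF was at -0.54. The list call was lost with an estimated correlation (adjusted p = 0.0954). IL6, an inflammatory cytokine, was at 39.5 CPM under avelumab, 55.7 under atezolizumab and 49 under durvalumab (-0.52 ± 0.067 against atezolizumab), with 20.7% of its exonic length overlapped by an antisense gene. CSF2, the GM-CSF gene, was at -0.54 ± 0.088. Cholesterol synthesis genes were higher in 3 of 25 (7 adjusted over the list alone), for example STARD4 (0.34), and fatty acid synthesis genes in 3 of 22 (4 adjusted over the list alone), for example SCD (0.33). Both calls were lost with an estimated correlation (adjusted p = 0.0954 each). Renal tubule genes were higher in 4 of 24 (4 higher and 3 lower adjusted over the list alone), among them CLDN2, a pore-forming claudin (0.78, uncertain with 10% of its exonic length overlapped), and CDH16, kidney cadherin (0.52), but the list was not called (adjusted p = 0.33), its median being -0.03 while the test pointed up.

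ITGB2-AS1, an antisense RNA that overlaps ITGB2 over 12.4% of its exonic length, was at -0.47 ± 0.093 for avelumab minus atezolizumab and 0.48 for durvalumab minus avelumab. The first call ended without atezolizumab replicate 1 or 3 or avelumab replicate 2 (adjusted p 0.0555 to 0.0754), the second without avelumab replicate 2 or 3 or durvalumab replicate 2 or 3 (0.0726 to 0.12). CXCL5, a neutrophil chemokine, was higher under durvalumab than under avelumab (0.33 ± 0.063), a call that ended without avelumab replicate 1 or 2 or durvalumab replicate 3 (0.0876 to 0.144). Between durvalumab and atezolizumab ZNF83, a zinc finger gene, was among the lowest p and did not pass (0.39 ± 0.074, adjusted p = 0.223). It passed with DESeq2 (0.0317) and with no filter (0.000485).

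Among the antibodies, 140 of 18886 genes differed in 786-O resistant cells (edgeR). Avelumab minus atezolizumab gave 159 higher and 69 lower genes and durvalumab minus avelumab 8 higher and 65 lower. Durvalumab minus atezolizumab gave 0 with edgeR, where 2251 genes were at an unadjusted p under 0.05 and DESeq2 called 3. The 140 genes became 93, 82 and 74 without atezolizumab replicates 1, 2 and 3, 71 and 88 without avelumab replicates 2 and 3 and 1160 without durvalumab replicate 1. The 228 genes for avelumab became 119, 73 and 81 without atezolizumab replicates 1, 2 and 3 and 98 and 118 without avelumab replicates 2 and 3. They became 501, 405 and 142 without durvalumab replicates 1, 2 and 3, which are not part of that contrast but share its filter, scaling and fit. The 73 genes became 35 and 41 without avelumab replicates 1 and 3 and 887, 37 and 34 without durvalumab replicates 1, 2 and 3. By a chi-square of counts, durvalumab replicates 1 and 2 differed more than any other 2 libraries of a group. Per degree of freedom it was 19.54, against 9.4 at most elsewhere. Whether durvalumab replicate 1 held the numbers of genes down was not tested. The count of 0 became 1 without atezolizumab replicate 2. By DESeq2 the 140, 228 and 73 genes became 289, 371 and 118. With no filter they became 692, 617 and 249 and the count of 0 became 80, and fitting only the 6 libraries compared gave 469 for the 228 and 46 for the 73.

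In the libraries labelled A498 resistant, few genes differed between antibodies. GADD45B, a stress-induced signalling protein, was at 142 ± 2.29 CPM under durvalumab, 121 ± 2.11 under atezolizumab and 124 ± 3.38 under avelumab (n = 3 each). Its log2 change was 0.24 ± 0.036 against atezolizumab (edgeR adjusted p = 0.00552) and 0.20 ± 0.035 against avelumab (0.0375). EGR1 was at 7.8 CPM under durvalumab and 11.1 under avelumab (-0.51 ± 0.081, 0.0133). LARP7 (-0.20 ± 0.05) and NUDT8 (0.48 ± 0.125) had the lowest p between avelumab and atezolizumab and did not pass (adjusted p = 1 for each). Interferon response genes gave 0 of 63 past the threshold for that pair with edgeR (0 adjusted over the list alone), with a median of 0.02. The list was called up at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.911).

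The GADD45B call against atezolizumab ended without atezolizumab replicate 2 or 3 or durvalumab replicate 1 (adjusted p 0.0582 to 0.246). Its call against avelumab ended without any 1 atezolizumab replicate, avelumab replicate 2 or 3 or durvalumab replicate 1 or 2 (0.0825 to 0.552). That of EGR1 ended without avelumab replicate 3 or durvalumab replicate 1 (0.101 to 0.483).

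Of 17510 genes in the libraries labelled A498 resistant, 2 differed among the antibodies, with 1170 at an unadjusted p under 0.05 (edgeR) and 1 by DESeq2. Avelumab minus atezolizumab gave 0 with edgeR and 0 with DESeq2, and 619 genes were at an unadjusted p under 0.05. Durvalumab gave 1 gene against atezolizumab and 3 against avelumab. The 2 genes became 4 and 0 without atezolizumab replicates 1 and 3, 48 and 5 without avelumab replicates 1 and 3, and 0, 0 and 89 without durvalumab replicates 1, 2 and 3. The count of 0 became 2 without atezolizumab replicate 1 and 1 and 4 without avelumab replicates 1 and 3. The 1 gene became 3, 0 and 0 without atezolizumab replicates 1, 2 and 3, 3 without avelumab replicate 1, and 0 and 42 without durvalumab replicates 1 and 3. The 3 genes became 1 without each atezolizumab replicate, 163 and 0 without avelumab replicates 1 and 3, and 0, 1 and 181 without durvalumab replicates 1, 2 and 3. With no filter the 2, 0, 1 and 3 genes became 50, 1, 9 and 54, by DESeq2 the 3 became 6, and fitting only the 6 libraries compared turned 1 into 4 and 3 into 0.

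**Figure D5:**
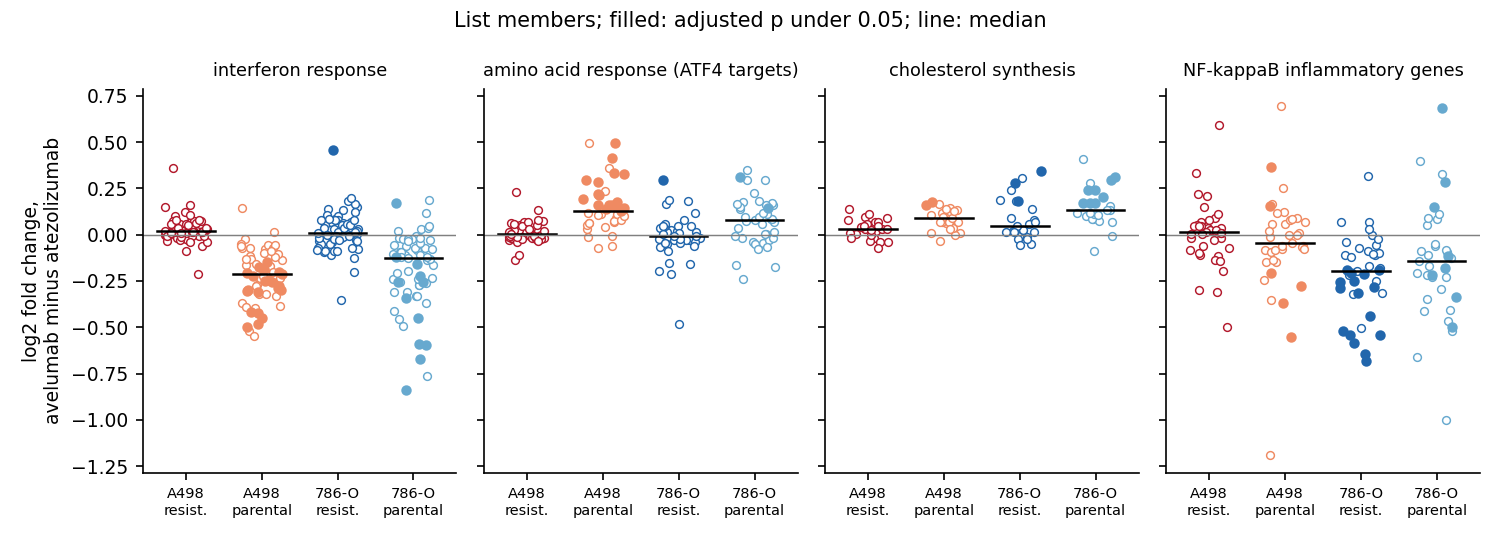
Log2 change, avelumab minus atezolizumab, of the members of 4 gene lists in each of the 4 cell states, 1 point per gene, filled where the adjusted p is under 0.05, with a line at the median. Interferon response genes centre on -0.21 in A498 parental and on 0.02 in the libraries labelled A498 resistant, and inflammatory genes centre on -0.20 in 786-O resistant.

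Antibody differences depended on the cell state for 173 of 19458 genes in A498 as labelled and for 119 of 19369 in 786-O (edgeR, 2 degrees of freedom). In A498, LGALS9 was at 6.95, 4.14 and 4.13 CPM under atezolizumab, avelumab and durvalumab in parental cells and at 31.8, 34.6 and 33.1 in the libraries labelled resistant. SLC38A2 was at 127, 160 and 151 CPM in parental cells and at 171, 170 and 162 in the libraries labelled resistant. IFI27, an interferon-induced gene, was at 199, 164 and 170 CPM and at 155, 157 and 169. In 786-O, TXNIP, which binds thioredoxin and limits glucose uptake, was at 32.7, 29.4 and 27.5 CPM in parental and 29.1, 44 and 32.7 in resistant cells. MAP7D2, a microtubule-associated protein, was at 11.8, 12.6 and 14 CPM in parental and 13.7, 24.4 and 15.6 in resistant cells.

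The 173 genes became 48 without A498 parental atezolizumab replicate 3, 77 and 283 without parental avelumab replicates 2 and 3 and 67 without parental durvalumab replicate 1. Among the libraries labelled A498 resistant they became 71, 42 and 99 without atezolizumab replicates 1, 2 and 3, 269 and 96 without avelumab replicates 1 and 3, and 74, 75 and 408 without durvalumab replicates 1, 2 and 3. The 119 genes became 57 without 786-O parental atezolizumab replicate 1, 54 and 56 without parental avelumab replicates 2 and 3, and 68 without parental durvalumab replicate 2. Among 786-O resistant libraries they became 60 without atezolizumab replicate 2 and 60 without replicate 3, 365, 63 and 79 without avelumab replicates 1, 2 and 3, and 1156 without durvalumab replicate 1. With no filter the 173 and 119 genes became 354 and 691, and by DESeq2 the 119 became 417. A batch difference that adds equally to every antibody cancels in this test. A difference between lines does not, and the line of the libraries labelled A498 resistant is in doubt. The 173 genes therefore cannot be assigned to resistance.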

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

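The tests that weigh the libraries labelled A498 resistant in this part were chosen only after the result was seen, while the splits of the libraries were planned. The resistant minus parental change differed between the lines as labelled for 16683 genes. On the log2 scale the difference, 786-O minus A498, was 7.39 for C1S, 6.83 for TNNT1, 5.81 for JUP and 5.07 for ANPEP. It was -10.14 for GSTP1, -9.74 for NNT, -9.41 for RAB34 and -0.35 for CD274. Of 30 splits of the libraries within line and antibody, 1, the real one, gave as many genes, and the highest other split gave 0. Other splits mix resistant and parental libraries, whose large differences then enter the spread and hold the counts down. The splits therefore do not decide whether chance made the difference between lines.

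This difference rests on libraries labelled A498 resistant whose profile is close to that of 786-O. Of 199 genes specific to 1 parental line (at least 5 CPM in it, under 0.1 CPM in the other), 10.05% (exact 95% interval 6.25 to 15.09) lay on the A498 side in these libraries, which argues against A498 cells that changed with resistance. The intervals in this paragraph treat genes as independent, which they are not, so they may be too narrow. The 8 A498-specific genes of at least 50 CPM, among them PTPRN, KCTD15 and ADD2, kept a median of 0.317% of the A498 parental level in these libraries. Their median was 0.0647% in 786-O resistant and 0.109% in 786-O parental, where it is low by the choice of genes. This argues against a large share of A498 cells in a mixed sample, but not against a small one. Of the A498-specific genes 9.7% lay on the A498 side in 786-O resistant libraries, which argues against labels swapped with that state. The change of these libraries from 3 of the 786-O parental libraries and that of 786-O resistant from the other 6 correlated across genes at r = 0.884 (0.893 with shared controls, where unchanged groups gave 0.503, with a covariance of 0.727 against a simulated 0.00278). All 786-O parental libraries carry 1 batch label, so a deviation of that batch would enter both changes. The simulation covers only the spread between libraries, so r cannot tell a shared change of the resistant libraries from such a deviation. That 786-O cells stand in place of A498 cells may be a candidate explanation but stays open, since it was found from these data and 88.06% (81.33 to 93.02) of the A498-specific genes lay on the 786-O side, where 90% was the bound set, although the interval holds that bound, 786-O resistant libraries gave 90.3% (83.98 to 94.73), and of the 786-O-specific genes 93.85% lay on the 786-O side, against 92.31% in 786-O resistant.

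Antibody differences depended on the cell state for 173 genes in A498 as labelled. With the line of the libraries labelled A498 resistant in doubt, these may be differences between lines and cannot be assigned to resistance. The largest of the 3 differences of differences, resistant minus parental, was 0.88 for LGALS9 (avelumab minus atezolizumab, adjusted p of the 2-degree test 6.24e-05), 0.50 for PCSK5 and -0.33 for SLC38A2 by the same pair. It was 0.37 for IFI27, 0.35 for PSMB9, -0.68 for CEP152 and -0.58 for CCN2, all for durvalumab minus atezolizumab. CCN2 and CEP152 are a matricellular protein and a centriole protein, and PCSK5 a proprotein convertase. Of 100 splits of the antibody labels, 2 gave as many genes, the real one included, and the highest other gave 242. A split above the real count points to a structure among these libraries other than the antibody, so chance is not excluded despite the small share.

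In 786-O, antibody differences depended on the cell state for 119 genes. For avelumab minus atezolizumab the difference was 0.75 for TXNIP (adjusted p of the 2-degree test 6.55e-05), 0.48 for AKAP12, a kinase anchor, and 0.46 for ARRDC3, an arrestin-domain gene. It was -0.96 for ATOH8 and -0.38 for UAP1L1. For durvalumab minus avelumab it was -0.80 for MAP7D2 and -0.58 for PCSK5. Of 100 splits 1, the real one, gave as many genes and the highest other gave 69. These splits regroup the antibodies within each state, so they also break up antibody differences that the states share. Such differences then enter the spread and can hold the other counts down. The splits therefore do not decide whether chance made the dependence on the cell state.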

How the results depend on the processing

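Thinning, the mitochondrial covariate, removal of the gene length trend and the comparison against 786-O parental libraries were chosen only after the result was seen, and the other alternatives were planned. No change of a named gene that passed the threshold turned its sign under an alternative run on it, while some CD274 values that did not pass did, such as that for A498 resistance (0.02, at its lowest -0.04). With RLE factors all 27 counts of genes and all 143 named genes stayed within 1.5 times or on their side of the threshold. So did the counts after thinning (579 in A498 parental and 559 in 786-O parental) and those without the length trend (714 and 792). Median changes moved by -0.01 in A498 and by under 0.01 in 786-O with RLE factors. The antibody comparisons moved with single libraries (98 such counts moved by over 1.5 times and 262 did not, over all comparisons) and with no filter (15 and 12), and in 3 against 3 libraries the depth and spread recovered 66% of 1.25-fold changes in the simulation of A498 parental cells. Where an alternative moved a count, the cause was not tested, except for the mitochondrial covariate, and that the strict filter and single pairs fit fewer genes or libraries.

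By DESeq2 the genes past the threshold numbered 417 for the 786-O interaction, 30 for durvalumab minus avelumab in 786-O parental, and 289 among the antibodies, 371 for avelumab minus atezolizumab, 3 for durvalumab minus atezolizumab and 118 for durvalumab minus avelumab in 786-O resistant. They numbered 7 for durvalumab minus avelumab in A498 parental, and 1 among the antibodies and 6 for durvalumab minus avelumab in the libraries labelled A498 resistant. With no filter they were 691 and 354 for the interactions in 786-O and A498. In 786-O parental they were 1400 among the antibodies, 643 for durvalumab minus atezolizumab and 299 for durvalumab minus avelumab. In 786-O resistant they were 692 among the antibodies and 617, 80 and 249 for the pairs, in the order avelumab minus atezolizumab, durvalumab minus atezolizumab and durvalumab minus avelumab. In A498 parental they were 1099 among the antibodies and 100 for durvalumab minus avelumab, and in the libraries labelled A498 resistant 50 among the antibodies and 1, 9 and 54 for the pairs.

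Fitting only the 6 libraries compared gave 12 genes for durvalumab minus avelumab in 786-O parental, 469 for avelumab minus atezolizumab and 46 for durvalumab minus avelumab in 786-O resistant, 1 for durvalumab minus avelumab in A498 parental, and 4 for durvalumab minus atezolizumab and 0 for durvalumab minus avelumab (1539 at an unadjusted p under 0.05 and 6 by DESeq2 in the full fit) in the libraries labelled A498 resistant. The strict filter gave 10787 genes for 786-O resistance and 0 for durvalumab minus avelumab in A498 parental (7 by DESeq2 and 1264 at an unadjusted p under 0.05 with the usual filter). The mitochondrial covariate left 68 genes in A498 parental and 373 in 786-O parental. A change of at least 2-fold was reached by 6185 genes for A498 resistance, 3909 for 786-O resistance and 7060 for the difference between lines.

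With a replicate block the counts were 300 among the antibodies, 438 for avelumab minus atezolizumab and 148 for durvalumab minus atezolizumab in 786-O parental. They were 347 among the antibodies and 410, 3 and 156 for the pairs in 786-O resistant, 112 for the A498 interaction, 5 for durvalumab minus avelumab in A498 parental and 1 in the libraries labelled A498 resistant. The replicate numbers did not pair the libraries: 2 of 36 pairs inside a state and 3 of 54 pairs across the states of a line correlated over 0.1, and 11 and 15 had their own number as the best match. With the block CD274 was at an adjusted p of 0.065 for the difference between lines and 0.0807 for 786-O resistance under durvalumab, RTN4R at 0.0761, COMTD1 at 0.0641, and GADD45B for durvalumab minus avelumab at 0.0685, while ZNF83 passed at 0.0411. The block changed no other call of a gene named here. With the block the share of higher genes for durvalumab minus avelumab in 786-O resistant was 25.6%, with no filter 23.7%, against 11%, and with DESeq2 that for avelumab minus atezolizumab was 53.6% against 69.7%.

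Leaving out 1 library at a time gave ranges over 4 counts in A498 parental: 233 to 892 genes among the antibodies, 141 to 759 for avelumab minus atezolizumab, 115 to 627 for durvalumab minus atezolizumab and 0 to 136 for durvalumab minus avelumab. In the same order the ranges were 299 to 1235, 244 to 1018, 104 to 536 and 0 to 222 in 786-O parental, 71 to 1160, 73 to 501, 0 to 1 and 34 to 887 in 786-O resistant, and 0 to 89, 0 to 4, 0 to 42 and 0 to 181 in the libraries labelled A498 resistant. The interactions ranged from 42 to 408 in A498 and from 54 to 1156 in 786-O. Resistance ranged from 17147 to 17455 genes in A498 as labelled and from 16187 to 16367 in 786-O, and the difference between lines from 16735 to 16861. Gene lists called ranged from 2 to 6 for durvalumab minus atezolizumab in 786-O resistant and from 4 to 12 for durvalumab minus avelumab in A498 parental. In the libraries labelled A498 resistant they ranged from 1 to 11 for avelumab minus atezolizumab, 6 to 11 for durvalumab minus atezolizumab and 3 to 12 for durvalumab minus avelumab. Among named genes, 87 such calls were lost and 7 gained, and 2075 stayed.

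With an estimated correlation camera called 1 list for A498 resistance, 4 for 786-O resistance, 1 for durvalumab minus atezolizumab in 786-O parental and 0 for each other antibody pair, where the preset correlation called 2 to 21 and unadjusted p-values under 0.05 numbered 7 to 23. Fry, which does not compare a list with other genes, called 32 and 33 lists for resistance in A498 and 786-O. For the antibody pairs, avelumab minus atezolizumab first and durvalumab minus avelumab last, it called 6, 3 and 1 in 786-O parental, 5, 0 and 4 in 786-O resistant, 2, 1 and 0 in A498 parental and 0, 0 and 0 in the libraries labelled A498 resistant.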

Other observations

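Comparisons with 786-O parental libraries, the tests of both patterns weighed in this part and the genes of the next paragraph were chosen only after the result was seen, while the splits of the libraries were planned. The libraries labelled A498 resistant were set directly against 786-O parental and 786-O resistant libraries. Against 786-O parental, all 63 tested interferon response genes were higher and 0 lower, with a median log2 change of 2.41, and 15 of 15 histone genes were higher. Ribosomal protein genes were lower in 74 of 74 (median -0.67), cholesterol synthesis genes higher in 24 and lower in 1 of 25 (median 0.75), and NRF2 targets, lower in every member against A498 parental, were higher in 13 and lower in 15 of 32. In all 15780 of 18901 genes passed (edgeR), a comparison across batch labels.

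786-O resistant libraries and those labelled A498 resistant differed for 13683 of 20752 genes (edgeR). CSF2 (3.23 ± 0.126) and CXCL8, a neutrophil chemokine (2.95 ± 0.107), were higher in 786-O resistant libraries, CXCL8 at 46.9 against 6.15 CPM. CLDN16 (-3.75 ± 0.08) and CLDN2 (-3.07 ± 0.082), claudins of tubular tight junctions, and PDGFRB, a sunitinib target (-3.27 ± 0.095), were lower, CLDN2 (uncertain, 10% of its exonic length overlapped) at 4.89 against 40.6 CPM. Interferon response genes were lower in 58 and higher in 1 of 63 (median -0.56). At least 2-fold differences numbered 533 higher and 744 lower genes, again across batch labels.

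Atezolizumab libraries stood apart in both parental states, where comparisons with them gave 320 to 763 genes and durvalumab minus avelumab at most 11, although the latter reached 100 (A498) and 299 (786-O) with no filter and 136 and 222 without A498 avelumab replicate 3 and 786-O durvalumab replicate 1, and the former fell to 115 and 104 without A498 durvalumab replicate 1 and 786-O durvalumab replicate 2. Of the genes that differed among the antibodies, at least 75.1% remained called after thinning to the smallest library and at least 92.2% after removing each library's gene length trend, which argues against library size and gene length as the whole cause. With the mitochondrial percent as a covariate 56% remained called in 786-O parental, which argues against it there, but 8.7% in A498 parental, where it may be involved: over the 643 genes whose call ended, the median size for avelumab minus atezolizumab went from 0.196 to 0.187, its standard error from 0.051 to 0.067 and 639 kept their sign, and the median ratio of size to error fell from 3.89 to 2.72 (2.97 with the errors alone changed, 3.55 with the sizes alone), so larger errors made up most of the loss. Genes higher under avelumab in both parental states numbered 45 (8.4 from independent lists) and lower in both 26 (5.0), while 4 and 6 went opposite ways. A pattern shared by the parental states stays open, since the match of their antibody profiles had an exact one-sided permutation p of 0.164 (adjusted p = 0.792 over 6 pairs of states).

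Interferon response genes were higher in 786-O resistant than in 786-O parental cells. The 24 leukocyte markers had a median of 0.031 CPM in 786-O resistant libraries (highest ITGAX, 1.55 CPM), which argues against RNA of leukocytes. The median change of the list lay 1.77 above that of the other 19306 tested genes (quartiles 1.07 to 2.88 against -0.37 to 0.55), which argues against scaling between libraries, since 1 factor per library moves all genes alike. The states share 0 batch labels, so a batch difference and a difference due to resistance, which was not tested apart from it, cannot be told apart.

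Chance was weighed by other splits of the same libraries. For the test among 3 antibodies, 1 of 100 splits gave as many genes as the real 704 in A498 parental (highest other 413). In 786-O parental 1 of 100 gave as many as 618 (308). These shares, not adjusted over the states, argue against chance in the grouping of these libraries in both parental states. Without 1 library the real counts fell as low as 233 and 299, under the highest other counts of 413 and 308. In 786-O resistant 3 of 100 gave as many as 140, a share not adjusted over the states, and the highest other gave 298. A split above the real count points to a structure among these libraries other than the antibody, so chance is not excluded there. For the 2 genes in the libraries labelled A498 resistant, 21 of 100 splits gave as many (highest other 267), so chance could not be excluded, and splits with many times the real count point to a structure among these libraries other than the antibody. For resistance, 1 of 100 splits gave as many genes as the real 17155 in A498 as labelled (highest other 0). In 786-O 1 of 100 gave as many as 16232 (highest other 1). Mixed splits carry the large differences between states into the spread, so how far the other counts lay below the real ones adds no support. The share of 1 in 100 argues only against a chance assignment of these libraries to the states. It cannot tell resistance from batch or culture. The antibodies taken singly, with 10 splits each, allow no share under 0.1: the real counts were 15388, 15647 and 15510 in A498 as labelled and 13932, 14168 and 13800 in 786-O, and the highest other was 0 in each.

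The 10 splits of an antibody pair are likewise too few for a share under 0.1. In A498 parental the real and highest other counts were 623 and 1 for avelumab minus atezolizumab, 515 and 0 for durvalumab minus atezolizumab and 11 and 0 for durvalumab minus avelumab. In 786-O parental they were 763 and 0, 320 and 216, and 0 and 0 in the same order. In 786-O resistant they were 228 and 0, 0 and 31, and 73 and 17. In the libraries labelled A498 resistant they were 0 and 20, 1 and 0, and 3 and 426, the last a split with many times the real count, which points to a structure of the samples.

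Some genes passed in the antibody comparisons of more than 1 state, though the states share no library, while the antibody profiles of no pair of states matched past the threshold (adjusted permutation p of 0.792 to 0.909). For durvalumab minus atezolizumab, 48 genes were higher in both parental states (4.1 from independent lists) and 5 lower in both (1.0), while 4 (1.8) and 7 (2.3) went opposite ways. For avelumab minus atezolizumab, 44 were higher in both 786-O states (4.3) and 8 lower in both (1.1), and 1 (2.6) and 2 (1.9) went opposite ways (permutation p = 0.264 for these states). Between A498 parental and 786-O resistant, 8 were higher in both (2.7) and 4 lower in both (1.1), while 8 (1.1) and 8 (2.6) went opposite ways. Resistant minus parental changes of the lines as labelled correlated at r = 0.221 across 18368 genes, with 4539 genes higher in both (3716.9 from independent lists) and 3988 lower in both (3104.5), while 2735 (3483.2) and 2553 (3312.8) went opposite ways. Each state has its own batch, and the line of the libraries labelled A498 resistant is in doubt. This overlap therefore cannot be assigned to a resistance change shared by 2 lines.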
